A study of Homo sapiens with 36 samples.

How the data were processed

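Total RNA of 2 human prostate cancer cell lines was measured on 36 Illumina HumanHT-12 arrays. ARCaP-E and ARCaP-M are established lines derived from a common parental line, the first with an epithelial and the second with a mesenchymal appearance. The arrays form 12 groups of 3, and the labels call the replicates independent experiments. In each line the groups were DMSO for 6 days, 5-aza-deoxycytidine at 1 µM over the same 6 days, vorinostat at 1 µM for 48 h, the combination of 1 µM vorinostat for 48 h with 20 µM genistein for 6 days, and a pair of groups whose titles carry an R, namely DMSO and 20 µM genistein for 6 days. For vorinostat alone the labels give no days of vehicle, so its time in culture may differ from that of DMSO and the combination. The labels do not explain the R. All genistein arrays carry it, so their control was the DMSO group with the same mark, called the R DMSO arrays here.

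The deposited scanner table holds intensity values per probe, linear and without normalization between arrays, from GenomeStudio 2010.2 per the labels, and a detection p-value per probe and array, per the file headers. The deposited series matrix holds intensity values that were quantile normalized between arrays and are linear. In the scanner table, 1 signal column carries a heading that names no sample and was left out, so that 1 ARCaP-M vorinostat array has no column of its own there, and a pair of columns shares 1 name and could be placed only in the R DMSO group of ARCaP-E. The other 33 columns had the rank order of the series matrix columns of the same names (largest difference 1.5 ranks, from ties). The series matrix names all 36 arrays and was therefore the source of the values. The plan made before the data were examined had named the scanner table with nec background correction and quantile normalization, which was run on the 35 usable columns as an added alternative.

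Series matrix values were background corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50) and taken to log2, with no further normalization. Of 47224 probes, 30110 carried 1 gene symbol, 8 several and 17106 none. Symbols were matched by Entrez ID for 30071 probes. A probe was kept when its detection p-value was below 0.01 on at least 3 of the 35 scanner columns, which left 21284 probes, 16446 of them with 1 symbol. For each of the 12205 genes so covered the probe with the highest mean was used, and 3350 genes had more than 1 kept probe. The deposited tables name no genome build, so no positions are given. Gene values are log2 differences of group means ± SE, with n = 3 arrays in each group. This SE rests on 1 variance per gene, pooled over all 12 groups by the limma model. It does not measure the spread of the groups compared. The spread differed between groups, so the SE can be too wide or too narrow for a single comparison. Where no probe of a gene was above background on any scanner column of the lower group, the fold is given as a lower bound. It was taken against that group's mean of the higher of the gene's value and the lowest value detected, per array.

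A single limma model of the 12 group means (24 residual degrees of freedom) gave moderated, two-sided tests of 21 comparisons, with Benjamini-Hochberg adjustment over the 12205 genes in each. Genes with adjusted p below 0.05 were called, and "rose" and "fell" are used only of these and of lists that passed their test. A difference between the lines or a departure from additivity was tested as a contrast of its own. Before the data were examined, 31 gene lists were fixed, and each was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 31 lists of a comparison. The estimated correlation between genes was run beside it. Among called list members the number is also given with the adjustment over the list alone.

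Genes were named by a rule set before the data were examined. In each direction it took up to 10 called genes with the largest change, no overlap between the 3 values of each group (which chance gives for 10% of genes) and detection on all arrays of the higher group. For differences of effects it took 5 per direction without the overlap condition. Up to 4 called members of each list discussed, and the drug targets HDAC1 to HDAC11, DNMT1, DNMT3A and DNMT3B, were named too. The text gives a part of the genes that rule names, and a part of the lists that passed their test.

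The alternatives set before the data were examined were no background correction, log2 of the series matrix values, median scaling after nec, no detection filter, detection on all arrays, all kept probes, a trended robust variance, a replicate block, the arrays of the compared groups alone, a limit of 1.5-fold, the other or both DMSO groups as control, camera with an estimated correlation or a replicate block, and each array left out in turn. After the data had been seen 6 more were added, namely nec with quantile normalization (the processing first planned), leaving out the arrays numbered 1 of vorinostat and combination, a block for the vorinostat and combination arrays, a block shared by the DMSO groups of ARCaP-E, a random block for sets of arrays, and calls shared by both DMSO controls. The number of arrays limits the precision. Data were simulated with the pooled spread of each gene and noise drawn independently per gene and array. To these 100 genes changed by 1.5-fold and 100 changed by 2-fold were added. Of them 83 and 94 were called for vorinostat in ARCaP-E and 83 and 96 for genistein in ARCaP-M. For additivity in ARCaP-E it was 47 and 89. False calls numbered 5, 7 and 6. The simulation held no deviation shared by the genes of an array, no unequal spread between groups and no difference between sets of arrays. The real arrays show these, so the simulated numbers need not hold for them.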

Results

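Gene expression was measured in ARCaP-E and ARCaP-M prostate cancer cells after vehicle, genistein (a soy isoflavone), vorinostat (a histone deacetylase inhibitor), both drugs, or 5-aza-deoxycytidine (an inhibitor of DNA methyltransferases), with 3 arrays in each of 12 groups. The study's title names a cooperation of genistein and vorinostat in inducing cell death. Between 14598 and 18897 of the 47224 probes were above background on each of the 35 arrays with a usable scanner column. The arrays fell into 3 sets by background signal. The lowest signal per array was 33.87 to 44.37 in the vorinostat and combination arrays, 76.13 to 87.63 in the DMSO and 5-aza-deoxycytidine arrays, and 17.88 to 22.25 in the genistein and R DMSO arrays. The set of vorinostat and combination arrays holds no DMSO array, so comparisons of these treatments with DMSO cannot be told apart from a difference between sets, while 5-aza-deoxycytidine, genistein, the line comparison in DMSO and the combination against vorinostat were each measured within 1 set. Array 1 of vorinostat in ARCaP-E stood apart, with 628 genes more than 2-fold from the mean of arrays 2 and 3, against at most 152 for any array of the other 11 groups.

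In DMSO the lines differed in epithelial genes. ARCaP-M had higher GZMB, which encodes the protease granzyme B (log2 5.77 ± 0.397, adjusted p = 8.51e-13, above background on 1 of 3 DMSO arrays of ARCaP-E), and higher SGK1, a serine/threonine kinase (3.95 ± 0.628). ALPL, an alkaline phosphatase, was at least 19.1-fold higher and the phosphate transporter SLC17A3 at least 12.7-fold higher in ARCaP-M. The TNF receptor family member TNFRSF19 (-5.50 ± 0.249, adjusted p = 3.93e-17), the scavenger receptor OLR1 (-5.03 ± 0.117), the iron-siderophore carrier LCN2 (-3.96 ± 0.317) and the detoxifying enzyme GSTM1 (-3.46 ± 0.145) were lower in ARCaP-M. Of 20 measured epithelial markers 11 were lower in ARCaP-M and 1 was higher (13 and 1 when adjusted over the list alone). The adhesion molecule CDH1 was at least 6.66-fold lower, and JUP, a junction protein (-2.06 ± 0.138), and the keratin KRT8 (-1.96 ± 0.174) were lower too. As a list the epithelial markers were lower (adjusted p = 5.46e-06, and adjusted p = 0.0973 with an estimated correlation).

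Mesenchymal markers did not differ as a list between the lines (0 of 17 higher and 3 lower, adjusted p = 0.498), and S100A4 was lower in ARCaP-M (-0.72 ± 0.179). Hypoxia and glycolysis genes were lower in ARCaP-M, with 7 of 20 lower and 1 higher (9 and 1 when adjusted over the list alone), among them the glucose transporter SLC2A1 (-2.79 ± 0.179) and the aldolase ALDOC (-2.41 ± 0.245), while NDRG1 was higher (2.31 ± 0.263). The list passed at adjusted p = 0.00189, and gave adjusted p = 0.721 with an estimated correlation. Cholesterol synthesis and uptake genes were higher, 7 of 20 by either adjustment, with SQLE at 1.12 ± 0.199 (adjusted p = 0.00441, and adjusted p = 0.721 with an estimated correlation). In all 3017 of 12205 genes were called, 1322 higher and 1695 lower in ARCaP-M, of which 1099 differed by at least 1.5-fold. With the R DMSO arrays of both lines instead, 2479 of these genes were called in the same direction.

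Vorinostat in ARCaP-E raised CRH, which encodes corticotropin-releasing hormone (2.60 ± 0.176, adjusted p = 1.2e-11), and lowered the collagen prolyl hydroxylase P3H2 (-2.23 ± 0.193, adjusted p = 1.27e-09). The inositol transporter SLC5A3 (-1.88 ± 0.139, above background on 2 of 3 vorinostat arrays), the stress-responsive chromatin protein NUPR1 (-1.81 ± 0.146) and the glycolytic regulator PFKFB4 (-1.58 ± 0.23) fell as well. GZMB rose by 2.76 ± 0.397, and by 1.83 without array 1 of vorinostat. Other genes that the naming rule took as raised also depended on that array and kept their calls without it. Among them were ABRAXAS1 (2.36, and 1.25 without it), ZNF682 (2.18 and 0.926) and CCBE1 (2.12 and 0.899). Interferon-stimulated genes fell as a list, with 24 of 34 lower and 3 higher by either adjustment, among them the antiviral GTPase MX1 (-1.50 ± 0.206), OAS2 (-1.37 ± 0.17) and the transcription factor IRF9 (-1.19 ± 0.169). That list passed at adjusted p = 0.000945, and gave adjusted p = 0.645 with an estimated correlation. Hypoxia and glycolysis genes fell, with 12 of 20 lower and 1 higher (13 and 1 when adjusted over the list alone), including the hexokinase HK2 (-1.54 ± 0.172) and the growth factor VEGFA (-1.45 ± 0.178). Their list had adjusted p = 0.0151, and adjusted p = 0.829 with an estimated correlation.

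Of the metal-binding metallothioneins 3 of 9 rose with vorinostat in ARCaP-E by either adjustment (MT1G by 1.43 ± 0.183), at adjusted p = 0.0151 for the list, and adjusted p = 0.682 with an estimated correlation. Neuronal and neuroendocrine genes, 6 of 15 higher and 1 lower by either adjustment, included the secretory proteins VGF (1.33 ± 0.139) and CHGB (1.07 ± 0.0893) and the enolase ENO2 (-1.53 ± 0.22). As a list they had adjusted p = 0.0362, and adjusted p = 0.426 with an estimated correlation. Of TGF-beta target genes 4 of 16 rose by either adjustment (ID1 by 1.20 ± 0.193). As a list they had adjusted p = 0.0272, and adjusted p = 0.645 with an estimated correlation. With median scaling the medians of these lists turned from 0.292 to -0.00494 for metallothioneins, from 0.068 to -0.421 for neuronal genes and from 0.244 to -0.184 for TGF-beta targets, while the median of all genes moved from -0.0929 to -0.623. The median of the neuronal genes was -0.0586 without array 2 of vorinostat. Genes commonly raised by HDAC inhibitors went both ways, with 4 of 20 higher and 5 lower (4 and 7 when adjusted over the list alone), the histone genes H2BC5 (-1.16 ± 0.231) and H2BC12 (-0.80 ± 0.205) among the lower. Their median was -0.00138, their mean 0.0469 and the list test pointed up without passing (adjusted p = 0.943). Without array 1 of vorinostat the median was -0.105 and the mean -0.171.

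Among the drug's targets HDAC1 (-0.55 ± 0.0965), HDAC6 (-0.64 ± 0.0978), HDAC7 (-0.64 ± 0.112, above background on 2 of 3 vorinostat arrays) and HDAC8 (-0.70 ± 0.0987, on 1 of 3) fell with vorinostat in ARCaP-E, while HDAC2 (0.26 ± 0.0735) and HDAC3 (0.28 ± 0.114) rose and turned negative with median scaling (-0.19 and -0.34). With that scaling both still lay above the median of all genes. Neither was called against the R DMSO arrays (adjusted p = 0.737 and 0.74). HDAC3 also lost its call without array 1 of vorinostat (0.19, adjusted p = 0.229), array 2 of vorinostat (adjusted p = 0.0684), array 1 of DMSO (adjusted p = 0.113) or array 2 of DMSO (adjusted p = 0.143). HDAC4 and HDAC11, at least 1.01-fold lower each, and HDAC5 fell to values not above background on the vorinostat arrays. HDAC9, above background on 2 of 3 vorinostat arrays, was at 0.025 (adjusted p = 0.907). Against the R DMSO arrays HDAC5 (adjusted p = 0.506) and HDAC11 (adjusted p = 0.131) were not called. HDAC2 (adjusted p = 0.0552), HDAC3 (adjusted p = 0.108), HDAC4 (adjusted p = 0.0574) and HDAC11 (adjusted p = 0.0702) were not called with the arrays of these groups alone. HDAC10 was not among the genes tested. In ARCaP-E 5449 genes were called with vorinostat, 1828 higher and 3621 lower (657 and 7952 with median scaling), and 1712 changed by at least 1.5-fold. With the arrays of these groups alone 3337 were called. Against both DMSO groups 3223 genes were called in the same direction, and 2725 with pooled DMSO arrays and the set of arrays as a random block.

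In ARCaP-M vorinostat raised the transcription factor gene FOS (2.73 ± 0.487, adjusted p = 5.63e-05), the galectin LGALS3 (1.92 ± 0.199) and the chemokine CCL5 (1.74 ± 0.222), and the membrane protein TSPAN7 by at least 4.26-fold. It lowered the mitochondrial enzyme SOD2 (-1.73 ± 0.207), the replication licensing factor CDT1 (-1.69 ± 0.201) and the NF-kB subunit RELB (-1.65 ± 0.132, adjusted p = 2.3e-10). G2/M and mitosis genes fell, 21 of 39 lower and 0 higher (22 when adjusted over the list alone), with KIF2C at -1.01 ± 0.206 and the kinase AURKA at -0.98 ± 0.17. As a list they had adjusted p = 0.000291, and adjusted p = 0.713 with an estimated correlation. G1/S and DNA replication genes fell too, with 11 of 33 lower and 1 higher by either adjustment (adjusted p = 0.0343, and adjusted p = 0.755 with an estimated correlation). Neuronal and neuroendocrine genes rose, 9 of 15 with 1 lower by either adjustment, VGF by 1.59 ± 0.139 (adjusted p = 0.0229, and adjusted p = 0.14 with an estimated correlation). Of 8 Wnt antagonists 5 rose and 0 fell (5 and 1 when adjusted over the list alone), among them DKK1 (0.59 ± 0.128) and DACT3 (0.96 ± 0.207). As a list they had adjusted p = 0.0292, and adjusted p = 0.14 with an estimated correlation.

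Endothelial markers were included as markers of another cell type, and 2 of the 3 measured rose with vorinostat in ARCaP-M by either adjustment, VWF by 1.69 ± 0.2 and ESAM by 1.08 ± 0.117 (adjusted p = 0.0454, and adjusted p = 0.14 with an estimated correlation). CDH1 was at least 2.32-fold higher and JUP rose by 1.24 ± 0.138, with 7 of 20 epithelial markers higher and 2 lower in a list that did not pass (adjusted p = 0.117). The probes of ribosomal RNA moved in ARCaP-M as well, with RNA28SN5 at -3.75 and RNA18SN5 at -1.78 against DMSO, and at -0.11 (adjusted p = 0.944) and -0.88 (adjusted p = 0.0761) against the R DMSO arrays. HDAC2 rose by 0.30 ± 0.0735, HDAC6 (-0.29 ± 0.0978) and HDAC8 (-0.33 ± 0.0987) fell, and HDAC1 was at -0.19 (adjusted p = 0.11). HDAC5 was at least 1.09-fold and HDAC7 at least 1.27-fold lower, and HDAC4, above background on 1 of 3 DMSO arrays, fell to values not above background. HDAC3 was at 0.23 (adjusted p = 0.113), HDAC9 at -0.30 (adjusted p = 0.103) and HDAC11 at -0.13 (adjusted p = 0.222). Against the R DMSO arrays HDAC2 (adjusted p = 0.837), HDAC4 (adjusted p = 0.481), HDAC5 (adjusted p = 0.752), HDAC6 (adjusted p = 0.24), HDAC7 (adjusted p = 0.245) and HDAC8 (adjusted p = 0.976) were not called, and HDAC4 and HDAC5 turned positive (0.10 and 0.042). HDAC4 lost its call without array 2 of vorinostat (adjusted p = 0.105) or array 1 of DMSO, and HDAC2 with median scaling (adjusted p = 0.979). HDAC6 lost its call without array 1 of vorinostat (adjusted p = 0.0621) or array 2 of DMSO (adjusted p = 0.0964) too. In ARCaP-M 5012 genes were called, 2035 higher and 2977 lower (702 and 4660 with median scaling), with 1539 at 1.5-fold or more. Against both DMSO groups 2912 were called in the same direction, and with the random block 2382.

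The vorinostat effect differed between the lines for 1102 genes, 774 with the more positive change in ARCaP-M and 328 with the more negative (1080 and 135 with median scaling), and for 713 without array 2 of DMSO of ARCaP-E. The count was 474 with the arrays of these groups alone and 1794 with the R DMSO arrays as control. TPD52L1, a tumour protein D52 family member, fell in ARCaP-E (-1.35) and rose in ARCaP-M (1.32, above background on 1 of 3 DMSO arrays there). ALOX5AP, the 5-lipoxygenase activating protein, rose in ARCaP-E (1.74) and fell in ARCaP-M (-1.53), a difference of -3.27 ± 0.308 (adjusted p = 2.49e-08). The difference was positive for interferon-stimulated genes, with 12 of 34 higher and 0 lower (16 when adjusted over the list alone, adjusted p = 1.7e-07, and adjusted p = 0.221 with an estimated correlation). Wnt target genes had a positive difference, 5 of 14 higher and 0 lower by either adjustment, at adjusted p = 0.00327, and passed with an estimated correlation too (adjusted p = 0.0459 with an estimated correlation).

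Genistein in ARCaP-E raised genes of cell division and lowered interferon-stimulated genes. The kinetochore genes CENPA (1.19 ± 0.234, adjusted p = 0.00317) and CENPF (1.02 ± 0.165, adjusted p = 0.00059), the securin PTTG1 (1.10 ± 0.222) and the uncoupling protein UCP2 (1.19 ± 0.244) rose. G2/M and mitosis genes rose as a list, 29 of 39 higher and 0 lower (37 when adjusted over the list alone), with a median of 0.806 (adjusted p = 6.91e-34, and adjusted p = 0.158 with an estimated correlation). G1/S and DNA replication genes rose as well, 16 of 33 higher and 0 lower (23 when adjusted over the list alone) at a median of 0.557 (adjusted p = 8.97e-17, and adjusted p = 0.224 with an estimated correlation). Interferon-stimulated genes fell, 16 of 34 lower and 0 higher (22 when adjusted over the list alone), among them MX1 (-1.40 ± 0.206), OAS2 (-1.26 ± 0.17), IFI27 (-1.25 ± 0.126, adjusted p = 7e-07) and EPSTI1, at least 1.51-fold lower. That list passed at adjusted p = 1.05e-19 and held with an estimated correlation (adjusted p = 0.0264 with an estimated correlation). Other genes that fell were the cold-sensing channel TRPM8 (-1.16 ± 0.192), the mucin MUC1 (-1.12 ± 0.195) and the keratin KRT20 (-1.09). In ARCaP-E 652 genes were called, 360 higher and 292 lower (255 and 68 with median scaling), 211 of them at 1.5-fold or more. The count was 171 without array 3 of genistein, 264 without array 2 of genistein, 257 without array 1 of R DMSO and 266 without array 2 of R DMSO. Against the DMSO arrays of the other set it was 3244, and 456 genes were called in the same direction against both.

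In ARCaP-M genistein raised the replication factor MCM10 (1.18 ± 0.202, adjusted p = 0.00128) and the helicase HELLS (0.97 ± 0.172), and lowered MUC1 (-1.10 ± 0.195), MX1 (-1.10 ± 0.206), IFI27 (-0.92 ± 0.126) and the corepressor RCOR2 (-0.99 ± 0.118, adjusted p = 1.49e-05). G1/S and DNA replication genes rose, 16 of 33 higher and 1 lower (24 and 1 when adjusted over the list alone), at a median of 0.646 (adjusted p = 1.94e-16, and adjusted p = 0.512 with an estimated correlation). G2/M and mitosis genes had 3 of 39 higher and 0 lower (12 when adjusted over the list alone), at a median of 0.312 (adjusted p = 1.95e-05, and adjusted p = 0.8 with an estimated correlation). Their median was 0.0816 without array 1 of R DMSO, 0.179 without array 3 of genistein and 0.469 without array 2 of genistein. Interferon-stimulated genes fell, 8 of 34 lower and 0 higher (13 and 1 when adjusted over the list alone, adjusted p = 0.000564, and adjusted p = 0.8 with an estimated correlation). Genes of the unfolded protein and integrated stress response rose as a list, though only 3 of 27 were called higher and 0 lower by either adjustment (adjusted p = 0.000564, and adjusted p = 0.8 with an estimated correlation).

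For genistein in ARCaP-M 557 genes were called, 320 higher and 237 lower (461 and 23 with median scaling), 139 of them at 1.5-fold or more, and 112 genes rose and 76 fell in both lines, where 9.439 and 5.67 would be shared by chance. With the genistein and R DMSO arrays of ARCaP-M alone limma called 0 genes, with 1977 at an unadjusted p below 0.05. The count was 69 without array 3 of genistein, 193 without array 1 of genistein, 195 without array 1 of R DMSO and 1079 without array 2 of genistein. A difference between the lines was called for 3 genes, TRIM16L (0.98 ± 0.177), IL13RA2 (0.94 ± 0.148) and LIMA1 (0.89 ± 0.161). Each had an adjusted p of 0.0563 without array 2 of R DMSO of ARCaP-E, and TRIM16L and LIMA1 lost their calls without several other arrays too. TRIM16L was above background on 0 of 3 R DMSO arrays of ARCaP-M, so the size of its difference is uncertain. G2/M genes had the more negative change in ARCaP-M, with a median difference of -0.411 and 0 single genes called (12 lower when adjusted over the list alone, adjusted p = 2.2e-16, and adjusted p = 0.506 with an estimated correlation).

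**Figure D1:**
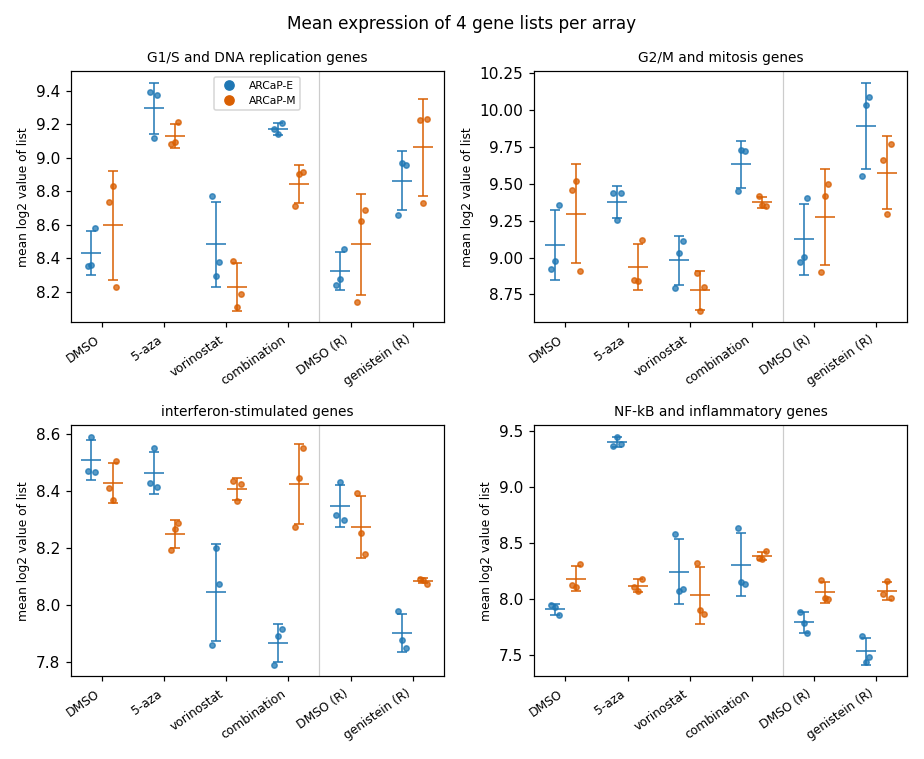
Mean log2 value per array of the G1/S, G2/M, interferon-stimulated and NF-kB lists in the 6 groups of ARCaP-E and ARCaP-M, with points for arrays, bars for mean ± SD of 3 arrays and a vertical line before the arrays marked R. G2/M genes of ARCaP-E averaged 9.895 with genistein against 9.125 in R DMSO, and NF-kB genes 9.402 with 5-aza-deoxycytidine against 7.911 in DMSO.

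The combination in ARCaP-E lowered NUPR1 (-3.17 ± 0.146, adjusted p = 9.37e-16, above background on 2 of 3 combination arrays), the actin-binding protein TAGLN (-2.68), MUC1 (-2.24 ± 0.195) and HK2 (-2.17 ± 0.172), and raised CRH (2.61 ± 0.176), the decoy receptor TNFRSF6B (2.45), the thymosin TMSB15A (2.75) and MT1G (2.34 ± 0.183). G1/S and DNA replication genes rose, 25 of 33 higher and 1 lower (26 and 1 when adjusted over the list alone), with PCNA at 1.75, MCM10 at 1.71 and DTL at 1.55 (adjusted p = 5.27e-08, and adjusted p = 0.562 with an estimated correlation). G2/M and mitosis genes rose, 25 of 39 higher and 0 lower (25 and 1 when adjusted over the list alone), with the checkpoint gene MAD2L1 at 1.68 (adjusted p = 3.68e-06, and adjusted p = 0.704 with an estimated correlation). Interferon-stimulated genes fell, 23 of 34 lower and 2 higher (25 and 2 when adjusted over the list alone), MX1 by -2.22 ± 0.206 (adjusted p = 1.27e-06, and adjusted p = 0.562 with an estimated correlation). Metallothioneins rose, 7 of 9 by either adjustment (adjusted p = 0.000884, and adjusted p = 0.562 with an estimated correlation). Their mean log2 value was 10.29 in DMSO and ran from 10.89 to 11.934 over the combination arrays (SD 0.6). MT1B was at 2.21, and at 1.11 without array 1 of the combination, where it lost its call (adjusted p = 0.157). It was above background on 0 of 3 DMSO arrays, so the size of its change is uncertain. Hypoxia and glycolysis genes fell, 13 of 20 with 1 higher (13 and 2 when adjusted over the list alone, adjusted p = 0.00179, and adjusted p = 0.704 with an estimated correlation). HDAC2 (0.50 ± 0.0735) and HDAC3 (0.54 ± 0.114) rose and were not called with median scaling (adjusted p = 0.0807 and 0.0651). HDAC6 fell (-0.48 ± 0.0978), and HDAC5, HDAC7 and HDAC8 were at least 1.03-fold, 1.63-fold and 1.49-fold lower, HDAC5 not called against the R DMSO arrays (adjusted p = 0.198). HDAC1 was at -0.20 (adjusted p = 0.0897) and HDAC9 at 0.20 (adjusted p = 0.274). HDAC4 was at -0.17 (adjusted p = 0.17, above background on 1 of 3 combination arrays) and HDAC11 was not called (adjusted p = 0.107, on 0 of 3). In ARCaP-E 6208 genes were called, 2529 higher and 3679 lower (1503 and 5259 with median scaling), 2449 of them at 1.5-fold or more. Against both DMSO groups 4253 were called in the same direction, and with the random block 3999.

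In ARCaP-M the combination raised TSPAN7 (at least 6.06-fold), TMSB15A (2.68), the calmodulin-binding protein NRGN (2.63, above background on 2 of 3 DMSO arrays), FOS (2.41) and VWF (2.15 ± 0.2), and lowered ALOX5AP (-1.97 ± 0.218, above background on 2 of 3 combination arrays), the RNA gene SNHG7 (-1.98) and KBTBD11 (-1.93). EOMES, a T-box transcription factor, was at least 2.61-fold lower. Metallothioneins were the 1 list that passed, 7 of 9 higher and 0 lower (9 when adjusted over the list alone), with MT1G at 1.49 and MT1X at 1.21 (adjusted p = 0.000908, and adjusted p = 0.508 with an estimated correlation). Their mean log2 value was 10.06 in DMSO and ran from 10.792 to 11.433 over the combination arrays. MT1B was at 1.97, and at 1.09 without array 1 of the combination, where it lost its call (adjusted p = 0.226). It was above background on 0 of 3 DMSO arrays here too, so the size of its change is uncertain. RNA28SN5 was at -3.65 here, and at -0.0038 (adjusted p = 0.998) against the R DMSO arrays. HDAC2 (0.33 ± 0.0735) and HDAC3 (0.31 ± 0.114) rose and turned negative with median scaling (-0.081 and -0.17). That scaling shifted the called genes as a whole towards lower values (849 higher and 6144 lower). HDAC6 (-0.34 ± 0.0978) and HDAC8 (-0.49 ± 0.0987, above background on 1 of 3 combination arrays) fell, and HDAC5, HDAC7 and HDAC11 were at least 1.08-fold, 1.26-fold and 1.05-fold lower. Of these only HDAC7 was called against the R DMSO arrays, where HDAC5 turned positive (0.083, adjusted p = 0.488). HDAC3 lost its call without array 1 of the combination (adjusted p = 0.199) or array 1 or 3 of DMSO, and HDAC6 without array 3 of the combination (adjusted p = 0.0635). HDAC1 was at -0.12 (adjusted p = 0.32), HDAC9 at -0.037 (adjusted p = 0.86) and HDAC4 was not called (adjusted p = 0.0885, above background on 0 of 3 combination arrays). In ARCaP-M 5509 genes were called, 2263 higher and 3246 lower (849 and 6144 with median scaling), 1841 at 1.5-fold or more. Against both DMSO groups 3355 were called in the same direction, and with the random block 2848.

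The combination effect differed between the lines for 878 genes, 505 of them with the more positive change in ARCaP-M and 373 with the more negative (262 and 499 with median scaling), and for 556 without array 1 and 508 without array 2 of DMSO of ARCaP-E. The growth factor binding protein IGFBP4 rose in ARCaP-E (1.84). In ARCaP-M IGFBP4 was above background on 1 and NUPR1 on 0 of 3 combination arrays, so the size of their line differences is uncertain. Interferon-stimulated genes had a positive difference, 22 of 34 higher and 0 lower (25 when adjusted over the list alone), at adjusted p = 5.11e-18, which held with an estimated correlation (adjusted p = 0.0375 with an estimated correlation). Their mean log2 value fell from 8.51 to 7.866 in ARCaP-E and was 8.429 and 8.424 in ARCaP-M.

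What genistein added to vorinostat was read from the combination against vorinostat, measured within 1 set of arrays. The labels give vorinostat alone for 48 h with no days of vehicle, while the combination had 6 days of genistein. Time in culture may therefore differ along with genistein. In ARCaP-E IGFBP4 (1.51 ± 0.178, adjusted p = 3.54e-06), the nuclease EXO1 (1.28 ± 0.153, above background on 2 of 3 vorinostat arrays), the apoptosis suppressor DDIAS (1.31 ± 0.16) and the topoisomerase TOP2A (1.25 ± 0.166) were higher with the combination, and GPRC5C (-1.10 ± 0.0951, adjusted p = 1.97e-08), the inhibitor of apoptosis BIRC7 (-1.59 ± 0.265), ALOX5AP (-1.49 ± 0.218) and NUPR1 (-1.36 ± 0.146) were lower, BIRC7 and NUPR1 above background on 2 of 3 combination arrays. G1/S genes were higher, 24 of 33 with 0 lower (28 when adjusted over the list alone, adjusted p = 1.12e-14, and adjusted p = 0.636 with an estimated correlation), and so were G2/M genes, 25 of 39 with 0 lower (33 when adjusted over the list alone, adjusted p = 1.08e-14, and adjusted p = 0.636 with an estimated correlation). Cholesterol synthesis and uptake genes were lower, 6 of 20 with 0 higher (7 when adjusted over the list alone, adjusted p = 0.000663, and adjusted p = 0.636 with an estimated correlation). Interferon-stimulated genes were lower, 7 of 34 with 2 higher (9 and 2 when adjusted over the list alone, adjusted p = 0.000663, and adjusted p = 0.636 with an estimated correlation), though their median of -0.206 became 0.00424 with median scaling, where that of all genes rose to 0.285. In ARCaP-E 1781 genes were called, 1179 higher and 602 lower (3688 and 147 with median scaling). The count was 2829 without array 1 of vorinostat and 1116 without array 1 of the combination. With the arrays of these groups alone the count was 39, where DDIAS, EXO1 and GPRC5C were called and IGFBP4, TOP2A, BIRC7, ALOX5AP and NUPR1 were not. Array 1 deviated alike in both groups (correlation 0.548 across genes, which are not independent replicates). Arrays 2 and 3 correlated with their own number at 0.462 and 0.354 and with the other at 0.448 and 0.372, so the numbers need not pair the samples. A replicate block over all groups without the R gave 1844 genes, and a block for the vorinostat and combination arrays alone, added after the data were seen, 2933.

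In ARCaP-M the combination had higher MCM10 (1.21 ± 0.202, adjusted p = 0.000764), DDIAS (1.08 ± 0.16) and TOP2A (0.91 ± 0.166) than vorinostat, and lower PNCK, a calmodulin-dependent kinase (-1.33 ± 0.127, adjusted p = 2.26e-07), KLHDC8B (-1.14 ± 0.12), MUC1 (-1.23 ± 0.195) and FCGBP (-1.13 ± 0.17). G2/M genes were higher, 13 of 39 with 0 lower (34 when adjusted over the list alone, adjusted p = 1.07e-23, and adjusted p = 0.248 with an estimated correlation). G1/S genes were higher, 18 of 33 with 0 lower (27 and 1 when adjusted over the list alone, adjusted p = 3.18e-22, and adjusted p = 0.234 with an estimated correlation). NF-kB and inflammatory genes were higher, 4 of 22 with 0 lower (7 when adjusted over the list alone), among them NFKB2 (0.82) and the adhesion molecule ICAM1 (0.74). The list had adjusted p = 1.01e-05, and adjusted p = 0.248 with an estimated correlation. The DNA methylation machinery was higher, 2 of 11 with 0 lower by either adjustment, DNMT1 by 0.88 ± 0.119 (adjusted p = 0.0104, and adjusted p = 0.145 with an estimated correlation). In ARCaP-M 527 genes were called, 282 higher and 245 lower (188 and 219 with median scaling). The count was 312 with the arrays of these groups alone and 1066 without array 1 of both groups. It was 175 without array 2 and 210 without array 3 of vorinostat, and 296 without array 1 and 340 without array 3 of the combination. Array 1 deviated alike here too (0.526), while arrays 2 and 3 correlated no better with their own number (0.294 and 0.275) than with the other (0.317 and 0.283). The same blocks gave 550 and 1149 genes.

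Part of the genes that genistein moved alone were moved in the presence of vorinostat as well. In ARCaP-E 249 of the 360 higher genes were higher in both comparisons where 34.78 would be shared by chance, and in ARCaP-M 107 of 320 where 7.394 would be. The shared lower genes numbered 93 of 292 against 14.4 and 72 of 237 against 4.757. The comparisons share no arrays, and their changes correlated across genes with r = 0.474 (rho = 0.424) in ARCaP-E and r = 0.579 (rho = 0.487) in ARCaP-M, where genes are not independent replicates.

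Additivity on the log2 scale asks whether the combination differed from the sum of the single effects. In ARCaP-E 38 genes departed from it, 29 upwards and 9 downwards. These were 294 and 12 with median scaling, and 71 and 26 with nec and quantile normalization. Without the arrays numbered 1 of vorinostat and combination they were 212 and 116. IGFBP4 (1.45 ± 0.251, adjusted p = 0.00836), the lipid droplet protein PLIN2 (1.06 ± 0.177, adjusted p = 0.00836) and HLA-DMB (1.03 ± 0.191, adjusted p = 0.0116) were higher than the sum, and WSB1 (-1.04 ± 0.196, adjusted p = 0.0118) was lower. Of the 31 lists 3 passed limma's camera for additivity in ARCaP-E and 7 in ARCaP-M, and a part of them is given here. In ARCaP-E interferon-stimulated genes lay above the sum, 2 of 34 called higher and 0 lower (5 when adjusted over the list alone, adjusted p = 0.000222, and adjusted p = 0.533 with an estimated correlation). In ARCaP-M limma called 0 genes, with 761 at an unadjusted p below 0.05. Without the arrays numbered 1 it called 64. There the unfolded protein and integrated stress response list lay below the sum at a median of -0.335 with 0 of 27 called by either adjustment (adjusted p = 2.88e-07, and adjusted p = 0.339 with an estimated correlation), and G2/M genes lay above it at 0.308 with 0 of 39 called by either adjustment (adjusted p = 2.14e-07, and adjusted p = 0.566 with an estimated correlation). In ARCaP-E limma called 0 genes with the arrays of these groups alone, with 841 at an unadjusted p below 0.05. The count there was 297 without array 1 and 128 without array 2 of vorinostat, 66 without array 2 of the combination, 18 without array 1 and 25 without array 2 of R DMSO, and 76 without array 1 and 20 without array 2 of genistein. A replicate block for the vorinostat and combination arrays gave 440 in ARCaP-E and 12 in ARCaP-M.

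**Figure D2:**
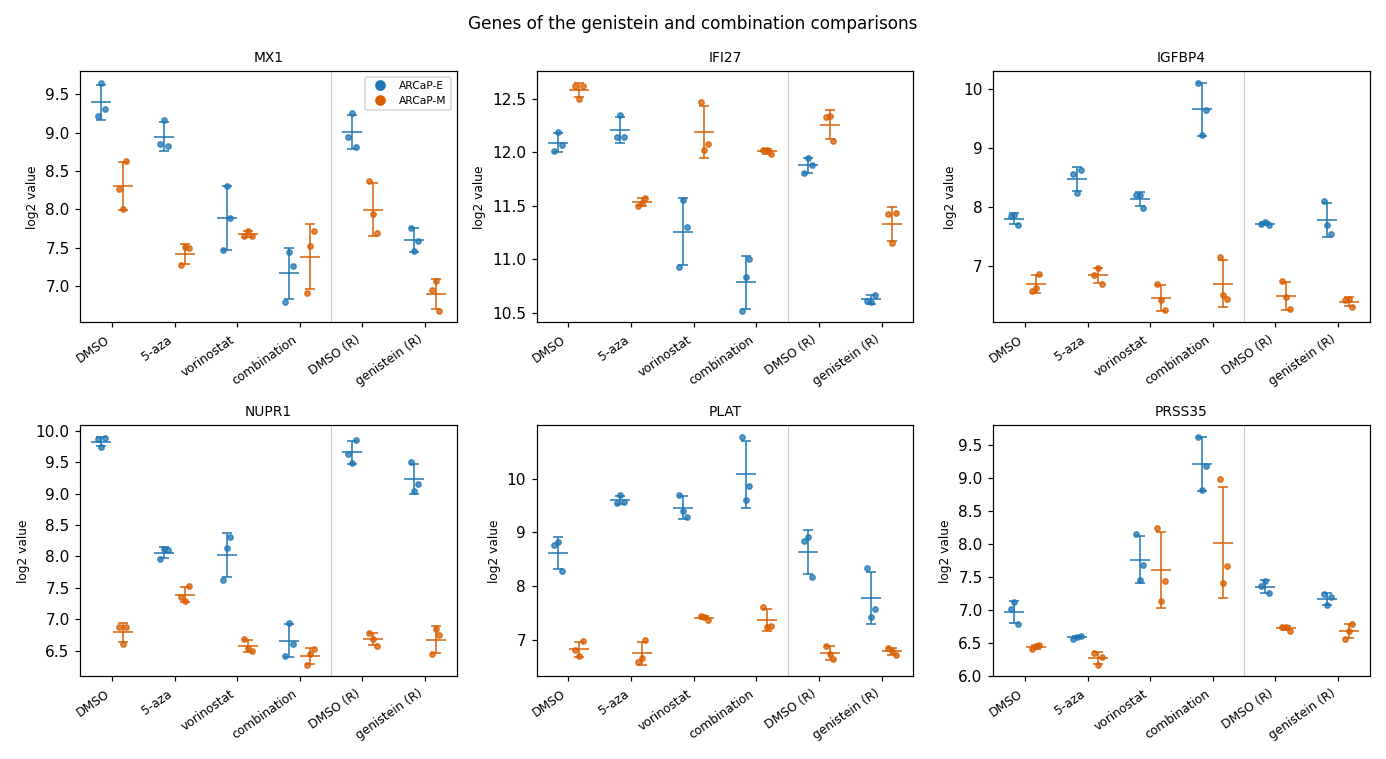
Log2 value per array of MX1, IFI27, IGFBP4, NUPR1, PLAT and PRSS35 in the 6 groups of ARCaP-E and ARCaP-M, with points for arrays, bars for mean ± SD of 3 arrays and a vertical line before the arrays marked R. IGFBP4 was 1.51 higher and NUPR1, above background on 2 of 3 combination arrays, fell by 1.36 on the log2 scale with the combination against vorinostat in ARCaP-E.

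What vorinostat added to genistein was read as the combination effect minus the genistein effect, each against the DMSO arrays of its own mark. The combination and its DMSO arrays lie in different sets, so these results cannot be told apart from a difference between sets. In ARCaP-E the cytokine gene TNF (2.76 ± 0.501, adjusted p = 0.000207), CRH (2.67 ± 0.249, above background on 2 of 3 R DMSO arrays) and the adhesion receptor ADGRG1 (2.44 ± 0.192) were higher, and TAGLN (-2.81 ± 0.525), NUPR1 (-2.75 ± 0.206, above background on 2 of 3 combination arrays) and P3H2 (-2.44 ± 0.273) were lower. NF-kB and inflammatory genes were higher, 8 of 22 with 2 lower by either adjustment (adjusted p = 0.00403, and adjusted p = 0.618 with an estimated correlation). In ARCaP-M the arginine deiminase PADI3 (2.13 ± 0.387) was higher and SNHG7 (-1.71 ± 0.32) was lower. Neuronal and neuroendocrine genes were higher in ARCaP-M, 5 of 15 with 0 lower (6 when adjusted over the list alone, adjusted p = 0.0294, and adjusted p = 0.2 with an estimated correlation), with a median of 0.519 that became -0.064 with median scaling, where that of all genes was -0.578. In ARCaP-E 3213 genes were called, 1222 higher and 1991 lower (655 and 3840 with median scaling). In ARCaP-M 2740 were called, 1010 higher and 1730 lower (318 and 5881 with median scaling). At 1.5-fold or more these were 1820 and 1415.

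Lists of cell death genes did not pass in any comparison against DMSO or of the combination against vorinostat. Of 25 pro-apoptotic genes the combination raised 6 and lowered 10 in ARCaP-E (median -0.0301, mean -0.057, the list test pointing up, adjusted p = 0.949) and raised 4 and lowered 6 in ARCaP-M (adjusted p = 0.981), by either adjustment. Of 12 anti-apoptotic genes it raised 3 and lowered 5 in ARCaP-E by either adjustment (adjusted p = 0.949) and raised 2 and lowered 5 in ARCaP-M (3 and 5 when adjusted over the list alone, adjusted p = 0.748). Of 22 p53 target genes it raised 7 and lowered 9 in ARCaP-E (7 and 10 when adjusted over the list alone, median -0.203, mean 0.00679, the list test pointing down, adjusted p = 0.949), with CDKN1A, an inhibitor of cyclin-dependent kinases, at 1.07 ± 0.282. Without array 1 of the combination CDKN1A was at 0.59 and lost its call (adjusted p = 0.0574).

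5-Aza-deoxycytidine in ARCaP-E raised inflammatory, germline and replication genes. ALOX5AP rose by 4.81 ± 0.218 (adjusted p = 7.6e-17), and the cytokines CXCL8 (3.63 ± 0.461), CXCL1 (3.24 ± 0.281), IL1B (2.68 ± 0.263) and IL1A (2.56 ± 0.19) rose. NF-kB and inflammatory genes rose as a list, 18 of 22 with 0 lower (21 when adjusted over the list alone) at a median of 1.59 (adjusted p = 1.59e-17), and held with an estimated correlation (adjusted p = 0.00561 with an estimated correlation). Cancer-testis and germline genes rose, 13 of 25 with 0 lower (15 when adjusted over the list alone), GAGE12G to at least 17.8-fold, though its probe may bind near-identical family members (adjusted p = 3.79e-07, and adjusted p = 0.0649 with an estimated correlation). G1/S and DNA replication genes rose, 29 of 33 with 0 lower (30 when adjusted over the list alone), among them the methylation maintenance factor UHRF1 (1.45 ± 0.199) and the thymidine kinase TK1 (1.43 ± 0.304). The whole list had adjusted p = 8.85e-15, and adjusted p = 0.229 with an estimated correlation. Unfolded protein and integrated stress response genes rose, 14 of 27 with 1 lower (15 and 2 when adjusted over the list alone), the chaperone HSPA5 by 1.32 ± 0.193 and MANF by 2.04 ± 0.294 (adjusted p = 0.000917, and adjusted p = 0.555 with an estimated correlation).

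The endothelial markers VWF (1.54 ± 0.2), ESAM (1.43 ± 0.117) and ENG (0.50) all rose with 5-aza-deoxycytidine in ARCaP-E, 3 of 3 by either adjustment (adjusted p = 0.000231, and adjusted p = 0.00561 with an estimated correlation). The steroid-converting enzyme AKR1C3 (-3.99 ± 0.211), GSTM1 (-2.68), the transcription factor EGR1 (-2.38 ± 0.364) and KRT20 (-2.28 ± 0.203) fell. NRF2 target genes fell, 8 of 16 with 0 higher (9 when adjusted over the list alone), the heme oxygenase HMOX1 by -1.25 ± 0.187 (adjusted p = 0.000584, and adjusted p = 0.229 with an estimated correlation). Wnt target genes fell, 5 of 14 with 0 higher (6 when adjusted over the list alone), AXIN2 by -1.43 ± 0.143 and SP5 by -1.33 ± 0.157 (adjusted p = 0.0208, and adjusted p = 0.0649 with an estimated correlation). Among the drug's targets DNMT1 rose by 1.04 ± 0.119 (adjusted p = 7.39e-08), DNMT3B, above background on 2 of 3 DMSO arrays, was at 0.10 (adjusted p = 0.456) and DNMT3A was not among the genes tested. In ARCaP-E 3793 genes were called, 1853 higher and 1940 lower (2379 and 1182 with median scaling), 1429 at 1.5-fold or more, and 3007 of them in the same direction against the R DMSO arrays, where 5708 were called. With the arrays of these groups alone 6533 were called.

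In ARCaP-M 5-aza-deoxycytidine lowered S100A4, a calcium-binding protein and mesenchymal marker (-4.57 ± 0.179, adjusted p = 3.26e-18), the sodium pump subunit FXYD2 (-4.03 ± 0.392), the sodium channel subunit SCNN1A (-3.04 ± 0.23) and AKR1C3 (-2.63 ± 0.211). ALOX5AP rose by 3.96 ± 0.218, and TXNIP, a regulator of thioredoxin, was at least 9.89-fold higher. Cancer-testis and germline genes rose, 19 of 25 with 0 lower by either adjustment at a median of 1.06, with PAGE2B at least 6.66-fold, SPANXD at least 2.56-fold and DAZL at least 2.15-fold higher (adjusted p = 2.02e-17), and held with an estimated correlation (adjusted p = 0.00256 with an estimated correlation). G1/S and DNA replication genes rose, 22 of 33 with 1 lower (25 and 2 when adjusted over the list alone, adjusted p = 2.23e-05, and adjusted p = 0.725 with an estimated correlation), while G2/M and mitosis genes fell, 15 of 39 with 1 higher by either adjustment, CCNB2 by -0.93 ± 0.23 (adjusted p = 0.00145, and adjusted p = 0.854 with an estimated correlation). Epithelial markers fell, 7 of 20 with 0 higher by either adjustment, SPINT2 by -1.94 ± 0.212 and EPCAM by -1.23 ± 0.251 (adjusted p = 0.00131, and adjusted p = 0.249 with an estimated correlation). Metallothioneins fell, 4 of 9 with 0 higher by either adjustment, MT1F by -2.08 ± 0.188 (adjusted p = 0.00246, and adjusted p = 0.725 with an estimated correlation). DNMT1 rose by 0.63 ± 0.119 (adjusted p = 0.000126) and DNMT3B, above background on 2 of 3 DMSO arrays, was at 0.22 (adjusted p = 0.078). In ARCaP-M 4090 genes were called, 2115 higher and 1975 lower, 1448 at 1.5-fold or more, and 3272 of them in the same direction against the R DMSO arrays.

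**Figure D3:**
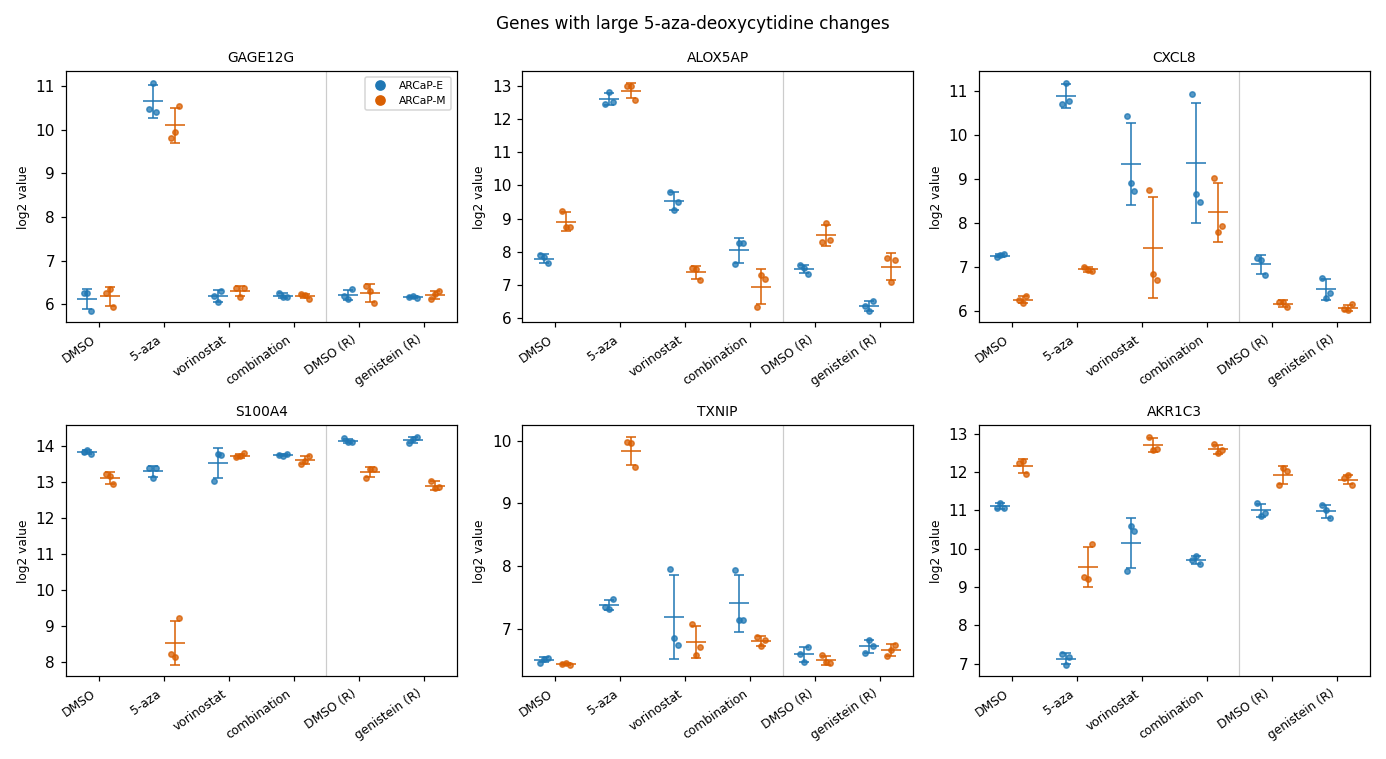
Log2 value per array of GAGE12G, ALOX5AP, CXCL8, S100A4, TXNIP and AKR1C3 in the 6 groups of ARCaP-E and ARCaP-M, with points for arrays, bars for mean ± SD of 3 arrays and a vertical line before the arrays marked R. GAGE12G lay between 9.804 and 11.08 on the 5-aza-deoxycytidine arrays and at most at 6.424 on the others, and S100A4 of ARCaP-M fell by 4.57 on the log2 scale.

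The 5-aza-deoxycytidine effect differed between the lines for 2573 genes, 1295 with the more positive change in ARCaP-M and 1278 with the more negative (712 and 1417 with median scaling). With the arrays of these groups alone it was 4985. The collagen cross-linking enzyme LOX rose in ARCaP-M (2.87) and was at -0.654 in ARCaP-E (adjusted p = 0.238), and HMOX1 rose in ARCaP-M (1.12) and fell in ARCaP-E (-1.25). EBI3, a cytokine subunit, and MANF rose in ARCaP-E (2.38 and 2.04) and fell in ARCaP-M (-0.858 and -1.20). NF-kB and inflammatory genes had the more negative change in ARCaP-M, 18 of 22 with 0 the other way (19 when adjusted over the list alone) and a median difference of -1.52 (adjusted p = 1.2e-16), which held with an estimated correlation (adjusted p = 0.0123 with an estimated correlation). In ARCaP-M alone 1 of the 22 was higher and 3 were lower (1 and 2 when adjusted over the list alone), at a median of -0.0312 (adjusted p = 0.706). Cancer-testis and germline genes had the more positive change in ARCaP-M, 12 of 25 with 2 the other way (14 and 2 when adjusted over the list alone, adjusted p = 1.23e-05, and adjusted p = 0.126 with an estimated correlation). G2/M genes had the more negative change there, 15 of 39 with 0 the other way (16 when adjusted over the list alone, adjusted p = 1.53e-07, and adjusted p = 0.63 with an estimated correlation).

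The DMSO arrays with and without the R differ in no treatment that the labels give, yet 2029 genes were called between them in ARCaP-E, 657 higher and 1372 lower in the R arrays (123 and 7286 with median scaling). In ARCaP-M 1798 were called, 476 higher and 1322 lower (68 and 9812 with median scaling). Of these 435 and 206 differed by at least 1.5-fold. In ARCaP-E the count was 3491 with the arrays of these groups alone. It was 1245 without array 2 and 1314 without array 3 of DMSO and 1325 without array 3 of R DMSO. In ARCaP-M it was 1169 without array 1 and 1092 without array 2 of DMSO and 1117 without array 2 of R DMSO. Interferon-stimulated genes averaged 8.349 in R DMSO and 8.51 in DMSO of ARCaP-E. Of the 31 lists 0 passed limma's camera in ARCaP-E and 1 in ARCaP-M, the cancer-testis and germline genes, with 2 of 25 higher and 1 lower by either adjustment (adjusted p = 0.025, and adjusted p = 0.954 with an estimated correlation). In ARCaP-E the arrays of the same number deviated alike in both groups (0.302, 0.292 and 0.561), and a replicate block shared by them left 1920 genes. In ARCaP-M they did not (-0.579, 0.275 and -0.538), but arrays of other numbers did. There array 1 of R DMSO correlated with array 3 of DMSO at 0.767, array 2 with array 1 at 0.495 and array 3 with array 2 at 0.531. The DMSO groups with and without the R need not be independent samples, so calls against both need not be independent either.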

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

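The tests of sets of arrays and of shared DMSO arrays were chosen only after the result was seen, and some hints of the others (high GZMB in array 1, the counts with arrays left out) were seen before they were written. The results listed first are those in which the effect of a treatment differed between ARCaP-M and ARCaP-E by limma's test of the difference itself, given as ARCaP-M minus ARCaP-E.

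The vorinostat effect differed for 1102 genes (713 without array 2 of DMSO of ARCaP-E). The more positive change in ARCaP-M was found for TPD52L1 (2.66), PCP4 (2.48), FXYD2 (2.29), FRAS1 (2.235) and ACSM3 (2.08). The more negative was found for GZMB (-3.39), ALOX5AP (-3.27), RNY4 (-2.54), IL32 (-2.05) and MMP10 (-1.94). Without array 1 of vorinostat in ARCaP-E the values were 1.89 for PCP4, -2.46 for GZMB and -1.765 for RNY4. FRAS1 was above background on 0 of 3 vorinostat arrays of ARCaP-E and on 1 of 3 DMSO arrays of ARCaP-M, TPD52L1 on 1 of 3 DMSO arrays of ARCaP-M and GZMB on 1 of 3 DMSO arrays of ARCaP-E, so the size of these differences is uncertain.

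The genistein effect differed for 3 genes, TRIM16L (0.98), IL13RA2 (0.94) and LIMA1 (0.89), each with adjusted p = 0.0563 without array 2 of R DMSO of ARCaP-E. TRIM16L was above background on 0 of 3 R DMSO arrays of ARCaP-M.

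The combination effect differed for 878 genes (508 without array 2 and 556 without array 1 of DMSO of ARCaP-E). The difference was positive for NUPR1 (2.795), TPD52L1 (2.57), PCP4 (2.54), FXYD2 (2.39) and FOS (2.29), and negative for GZMB (-2.37), ALOX5AP (-2.215), ANPEP (-2.03), IGFBP4 (-1.83) and ABHD3 (-1.70). In ARCaP-M NUPR1 was above background on 0, IGFBP4 on 1 and ALOX5AP on 2 of 3 combination arrays, and TPD52L1 on 1 of 3 DMSO arrays. In ARCaP-E it was 1 of 3 DMSO arrays for GZMB and 2 of 3 combination arrays for NUPR1, so the size of these differences is uncertain. Without array 1 of the combination in ARCaP-E FXYD2 was at 1.67. FOS lost its call without either of arrays 1 and 2 of DMSO in each line, array 2 or 3 of the combination in ARCaP-E or array 1 of the combination in ARCaP-M (highest adjusted p = 0.125).

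The 5-aza-deoxycytidine effect differed for 2573 genes. The difference was positive for LOX (3.52), BEX2 (2.60), TXNIP (2.53), TNFRSF19 (2.45) and HMOX1 (2.38), and negative for S100A4 (-4.035), COXFA4L3 (-3.85), C6orf58 (-3.49), EBI3 (-3.24) and MANF (-3.24). TXNIP was above background on 0 of 3 DMSO arrays and TNFRSF19 on 1 of 3 5-aza-deoxycytidine arrays of ARCaP-M, so the size of these differences is uncertain.

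Array 1 of vorinostat in ARCaP-E stood apart, with 407 genes more than 2-fold above and 221 more than 2-fold below arrays 2 and 3. Its deviation correlated across genes with the vorinostat effect in ARCaP-M at only 0.0138, which argues against a stronger form of the ARCaP-M response. That effect was measured in the other line and across sets of arrays. A stronger response of that culture in the manner of ARCaP-E was not tested and stays open. RNA of ARCaP-M cells in the sample may contribute and stays open, with a median deviation of 0.262 ± 0.21 over 40 genes higher in ARCaP-M, and so does RNA of cells treated with 5-aza-deoxycytidine, with 0.215 ± 0.24 over 32 genes. For these medians ± is a standard error over the genes, which are not independent replicates, and not a spread between arrays. Signal of single probes would explain at most a part, and as a part stays open. Probes of a gene shared much of the deviation, with a correlation of 0.571 ± 0.012 over 3350 genes that are not independent replicates, though below the 0.757 of the 5-aza-deoxycytidine effect. The deviation also correlated with that of array 1 of the combination in ARCaP-E (0.548), of vorinostat in ARCaP-M (0.356) and of the combination in ARCaP-M (0.227). Array 1 of vorinostat in ARCaP-E had 14603 probes above background, against 15889 and 15975 on arrays 2 and 3. Its 90th percentile of signal was 4.996 times the median, against 6.165 and 5.782. Whether this bears on the deviation was not tested.

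Cell cycle genes were higher with genistein in both lines. A difference between sets of arrays is excluded by the design, since the genistein and R DMSO arrays lie in 1 set. Within another set the G2/M genes were higher in the combination than in vorinostat too, by a median of at least 0.603 ± 0.051 in each line. Here ± is a standard error of the median over the genes of a list, which are not independent replicates. It does not measure the spread between arrays. A single array is argued against in ARCaP-E, where the lowest median of the G2/M genes with 1 array left out was 0.657 ± 0.045. In ARCaP-M a single array could still matter, since the G1/S median stayed at 0.476 ± 0.088 or more while that of the G2/M genes was 0.0816 without array 1 of R DMSO. A response of the cells to genistein stays among the open explanations.

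The effects of vorinostat and 5-aza-deoxycytidine correlated across genes in ARCaP-E with r = 0.484 (r = -0.0529 in ARCaP-M) when the R DMSO arrays were the control of vorinostat, where genes are not independent replicates. With shared DMSO arrays r was 0.462, and 0.498 in data simulated without effects, so that value shows nothing by itself. The covariance was 0.0929 with the R DMSO arrays as the control of vorinostat and 0.0844 with shared arrays, against 0.0094 simulated without effects. That argues against noise of the shared DMSO arrays, drawn independently per array, as the whole cause. The R DMSO arrays deviated like the DMSO arrays of the same number (0.302, 0.292 and 0.561). They need not be independent of them, so a part from shared DMSO samples stays open. Array 1 of vorinostat may contribute and stays open, since without it the covariance was 0.0633. A response common to both drugs was not tested apart from it.

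Other splits of the same arrays were fitted in the same way. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 3017 genes between the lines (highest other 0), 5449 for vorinostat in ARCaP-E (24), 652 for genistein in ARCaP-E (135), 6208 for the combination in ARCaP-E (8), 3793 for 5-aza-deoxycytidine in ARCaP-E (0) and 2029 for R DMSO against DMSO in ARCaP-E (0). In ARCaP-M it called 5012 for vorinostat (0), 557 for genistein (94), 5509 for the combination (0), 527 for the combination against vorinostat (82), 4090 for 5-aza-deoxycytidine (0) and 1798 for R DMSO (9), and in each of these 1 split, the real one, called as many. For the combination against vorinostat in ARCaP-E the real split called 1781 and the highest other 2696, and 3 splits called as many. Of the 4 splits that part the replicates of each number the highest other called 21. The others set replicates of at least 1 number together, which points to a structure of the samples, though the numbers need not pair them.

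For comparisons of more groups 100 splits were drawn. They mix treatments, and in line differences the lines too, so their counts carry these differences and decide nothing about chance. For the combination effect minus the genistein effect 4 splits in ARCaP-E (real 3213, highest other 4753) and 1 in ARCaP-M (real 2740, highest other 2354) called as many genes. For departure from additivity it was 22 splits in ARCaP-E (real 38, highest other 5151) and 100 in ARCaP-M (real 0, highest other 3242). As many were called too for the line differences of the vorinostat (16 splits, real 1102, highest other 3443), genistein (31 splits, real 3, highest other 2988), combination (14 splits, real 878, highest other 4441) and 5-aza-deoxycytidine effects (5 splits, real 2573, highest other 3533). Counts several times the real one can come from this mixing, so they say nothing of a structure of the samples.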

How the results depend on the processing

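Tests chosen only after the data were seen were the fits without the arrays numbered 1 of vorinostat and combination, the block for those arrays, the block shared by the DMSO groups of ARCaP-E, the random block for sets of arrays and the calls shared by both DMSO groups. The processing first planned, nec with quantile normalization, was run as an alternative once the scanner table was seen to lack a named column. A block for the slide of each array was not run, since the deposited tables name no slides. Counts not given here stayed within 1.5 times the reported one. Unless said otherwise the cause of a change was not tested. Genes near background are limited by the signal over it, and the number of arrays by 3 per group.

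At 1.5-fold or more, a stricter limit by construction, the counts were 1099 between the lines, and in ARCaP-E 1712 for vorinostat, 211 for genistein, 2449 for the combination, 477 for the combination against vorinostat, 1820 for the combination minus genistein, 1429 for 5-aza-deoxycytidine and 435 for R DMSO. In ARCaP-M they were 1539, 139, 1841, 189, 1415, 1448 and 206 in the same order, and for the line differences 725 for vorinostat, 572 for the combination and 1606 for 5-aza-deoxycytidine.

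With nec and median scaling, where the median of all genes moved to -0.623 for vorinostat, 0.285 for the combination against vorinostat, 0.249 for additivity and -0.531 for R DMSO in ARCaP-E, the counts were 8609, 3835, 306 and 7409, and 323 for genistein. In ARCaP-M that median was -0.578 for the combination minus genistein, -0.233 for additivity and -0.88 for R DMSO, and the counts were 6199, 1 and 9880. The line difference of genistein had 1 gene. Relative to the median of all genes none of the called lists changed its direction. Median scaling moved the balance of higher and lower genes more than the counts. In ARCaP-E it gave 657 higher and 7952 lower for vorinostat, 255 and 68 for genistein, 1503 and 5259 for the combination, 3688 and 147 for the combination against vorinostat, 655 and 3840 for the combination minus genistein, 294 and 12 for additivity, 2379 and 1182 for 5-aza-deoxycytidine and 123 and 7286 for R DMSO. In ARCaP-M the pairs were 702 and 4660, 461 and 23, 849 and 6144, 188 and 219, 318 and 5881, 1 and 0, 2066 and 1665 and 68 and 9812 in the same order, and 996 and 1640 between the lines. The line differences had 1080 and 135 for vorinostat, 262 and 499 for the combination and 712 and 1417 for 5-aza-deoxycytidine.

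With detection on all arrays, which tests fewer genes, the counts were 3579 for vorinostat, 23 for additivity and 1333 for R DMSO in ARCaP-E and 626 for R DMSO in ARCaP-M. With all kept probes, which tests more, they were 8942 for vorinostat, 9917 for the combination, 2724 for the combination against vorinostat, 4980 for the combination minus genistein and 4091 for R DMSO in ARCaP-E. In ARCaP-M they were 8091 for vorinostat, 8966 for the combination, 4417 for the combination minus genistein, 6204 for 5-aza-deoxycytidine and 3697 for R DMSO. Without a detection filter R DMSO in ARCaP-M had 2801.

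With the arrays of the compared groups alone, the variance comes from these fewer arrays and not from all 12 groups. The spread differed between groups. In ARCaP-E the SD across genes around the group mean was 0.366, 0.211 and 0.193 for the vorinostat arrays. It was 0.0618, 0.0795 and 0.0607 for the 5-aza-deoxycytidine arrays. Counts moved in both directions. In ARCaP-E they were 3337 for vorinostat, 39 for the combination against vorinostat, 6533 for 5-aza-deoxycytidine and 3491 for R DMSO. Additivity had 0 by limma there (841 at an unadjusted p below 0.05). In ARCaP-M the counts were 312 for the combination against vorinostat and 0 by limma for genistein (1977 unadjusted). The line differences had 474 for vorinostat, 4985 for 5-aza-deoxycytidine and 0 by limma for genistein (880 unadjusted).

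With the other DMSO group as control genistein had 3244 in ARCaP-E and 3014 in ARCaP-M, 5-aza-deoxycytidine 5708 in ARCaP-E, and the line differences 1794 for vorinostat and 0 by limma for genistein (592 unadjusted). With both DMSO groups pooled genistein had 1219 and 1133 and these line differences 1694 and 5. With the random block vorinostat had 2725 in ARCaP-E and 2382 in ARCaP-M, and the combination 3999 and 2848. Called in the same direction against both DMSO groups were 3223 for vorinostat in ARCaP-E, 2912 in ARCaP-M and 3355 for the combination in ARCaP-M.

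The replicate block left all counts within 1.5 times (for R DMSO 1984 in ARCaP-E and 1739 in ARCaP-M), and a block shared by both DMSO groups of ARCaP-E gave 1920. The block for vorinostat and combination arrays gave 2933 and 1149 for the combination against vorinostat, and 440 and 12 for additivity. Without the arrays numbered 1 additivity had 328 and 64, and the combination against vorinostat in ARCaP-M 1066. With nec and quantile normalization additivity had 97 and 3, and the line difference of genistein 6.

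With each array left out in turn the counts ranged from 2313 to 2625 between the lines. In ARCaP-E they ranged from 4438 to 5483 for vorinostat, 171 to 967 for genistein, 5268 to 5919 for the combination, 1116 to 2829 for the combination against vorinostat, 2517 to 3264 for the combination minus genistein, 18 to 297 for additivity, 2821 to 3379 for 5-aza-deoxycytidine and 1245 to 1482 for R DMSO. In ARCaP-M they ranged from 4172 to 4475, 69 to 1079, 4409 to 5095, 175 to 717, 2101 to 2723, 0 to 2, 3158 to 3695 and 1092 to 1613 in the same order. The line differences ranged from 713 to 1640 for vorinostat, 0 to 18 for genistein, 508 to 921 for the combination and 2023 to 2607 for 5-aza-deoxycytidine.

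With an estimated correlation limma's camera called 1 list for genistein in ARCaP-E, 2 for 5-aza-deoxycytidine in ARCaP-E, 1 for 5-aza-deoxycytidine in ARCaP-M, and 1, 1 and 2 for the line differences of vorinostat, the combination and 5-aza-deoxycytidine. In each other comparison it called 0, with between 0 and 4 lists at an unadjusted p below 0.05.

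Among named genes some changed sign. With median scaling the vorinostat values in ARCaP-E were -0.11 for BIRC2, -0.12 for ETV4, -0.26 for AXL, -0.13 for DKK3, -0.19 for HDAC2 and -0.34 for HDAC3. Each of these lay above the median of all genes with that scaling. BCL2L2 was at 0.018 in the combination against vorinostat in ARCaP-E. For the combination in ARCaP-M FHL2 was at -0.092, HDAC2 at -0.081 and HDAC3 at -0.17, and for the combination minus genistein there SYP was at -0.071 and RPL5 at -0.015. With the other DMSO group RNA28SN5 was at 1.78 for 5-aza-deoxycytidine in ARCaP-E and CFLAR at 0.58 for the combination in ARCaP-E, and at 0.043 with both groups pooled, with or without the random block. In ARCaP-M that group gave HDAC5 0.083 and SLC7A11 0.070 for the combination, SESN1 -0.055 for genistein, and BAG1 0.070, HDAC5 0.042, PLK3 0.043 and HDAC4 0.10 for vorinostat. Between the lines HSPB8 was at 0.017 in the R DMSO arrays. With the combination compared directly with genistein in ARCaP-E SLBP was at -0.0075 and HLA-G at -0.0092.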
